A study of Rattus norvegicus with 12 samples.

How the data were processed

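RNA was measured on 12 single-colour Agilent arrays, 3 in each of 4 groups. Small hepatocytes are hepatocytic progenitor cells of the rat liver. Per the labels, these came from F344 rats, were sorted magnetically for the surface protein CD44 on day 9 after plating, had been grown on Matrigel, and were collected at passage 2 after 3 h on dishes coated with laminin-111 (group LN111), laminin-511 (LN511) or Matrigel (Mat), a basement membrane extract. The medium was serum-free, with 10 ng/mL EGF and 10 mM nicotinamide. Mature hepatocytes freshly isolated from livers (MH) served as the control. Cd44 was the sort marker of the cultured cells, so its difference from MH is not a finding. The labels do not say that replicates came from separate animals or cultures, so the p-values measure the spread between these samples, which may be technical.

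Per the labels' protocols, 100 ng of total RNA was labelled with Cy3 for each array. Per the file headers, the scanner images were read with Agilent Feature Extraction (version 10.7 per the submitters' processing notes). The processed signal is a linear intensity that, per the file headers, was background-subtracted and detrended in space and by a multiplicative factor, with surrogate values in place of low signals. The authors' deposited value table holds that same intensity on a linear scale, with no scaling between arrays. No value differed from the scanner files by more than 0.0072 on the log2 scale, and its column medians were 61.8, 59.0 and 45.1 (LN111), 45.5, 49.0 and 43.6 (LN511), 85.5, 90.9 and 57.5 (Mat) and 27.5, 27.6 and 23.6 (MH). Its scale was thereby settled, it is not centred, and as a single-colour intensity it has no direction. No statistical test by the authors is given in the sources used here.

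From the deposited intensity, the log2 of the processed signal minus the 75th percentile of each array was computed. Control spots and spots with an outlier mark were left out, and spots of a probe were averaged, which kept 45489 probes and lost 109. Of 45598 probes, 21102 were named through their accession in the RefSeq gene table supplied, 2615 through another RefSeq accession, 5171 through the symbol in the file and 345 through an older symbol. The file's own name was kept for 16365, and some of these names are old. Gene names numbered 35911. A gene was tested if a probe was well above background on all 3 arrays of at least 1 group in the fit, and its probe of highest mean signal stood for it. Placeholder names (clone, LOC or similar) made up 6173 of the 18953 genes tested with MH and 5712 of the 17932 tested without. No genome was used.

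Genes were tested two-sided with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Comparisons with MH came from 1 fit of all 12 arrays, in which "cultured" is the mean of LN111, LN511 and Mat. Comparisons among substrates came from 1 fit of the 9 cultured arrays, as did a moderated F test over the 3 groups. The groups, the tests, 34 gene lists, the processing alternatives and the rule for named genes were fixed before the data were examined. Lists with at least 5 tested members were tested with camera at an inter-gene correlation of 0.01, and beside it with camera and an estimated correlation and with fry. Errors beside log2 differences are standard errors (SE) of the fit. For genes not well above background on any array of 1 group, "at least N-fold" sets the mean of the brighter group against the mean, in the dimmer group, of the higher of each array's lowest signal well above background and the probe's own signal.

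The rule for named genes took, for cultured against MH, the 10 largest increases and 10 largest decreases among genes with adjusted p under 0.05, all 9 cultured arrays on 1 side of the 3 MH arrays, signal well above background on all arrays of the higher group and no placeholder name. For each substrate comparison it took the 5 largest in each direction with 3 arrays separated from 3, or, where none passed, the 5 smallest p-values among genes without a placeholder name as not passing. It added in every comparison Cd44, Alb, Afp, Krt19, Sox9, Epcam, Hnf4a, Itga3, Itga6, Itgb1, Dag1, Cyp7a1 and Mki67, and up to 4 members with the smallest p from each list described. The largest differences measured in both groups were added to the names after their values were seen. Gene symbols are those of the table or file. Array quality is given where the results are.

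The tests were run on simulated data before use, with 100 genes changed by each fold in 10 simulations per comparison. For cultured against MH, 53.5% of 2-fold and 84.6% of 4-fold changes were recovered, and 5.28% of calls were false. These values were 35.9%, 76.4% and 5.79% for LN111 against MH, 33.8%, 74.6% and 6.07% for LN511 against MH, and 39%, 72.1% and 5.77% for Mat against MH. They were 41.1%, 75.2% and 4.98% for LN111 against Mat, 34.6%, 75.5% and 5.25% for LN511 against Mat, and 36.4%, 75.3% and 6.13% for LN111 against LN511. The simulated noise was independent between genes and arrays, few genes changed, equally up and down, and no scaling step was run. The real arrays differ in these respects, so the shares recovered and false need not hold for them. The number of arrays limits the precision.

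The files place the arrays on 2 slides. Slide 1 held the 3 MH arrays and Mat replicates 1 and 2, and slide 2 held Mat replicate 3 and the LN111 and LN511 arrays, so that neither laminin shares a slide with MH. Results are therefore also given with the slide as a block and within a slide. Whether the replicate number pairs cultured samples was checked by the correlation, over genes, of deviations from the group means. For same numbers it was 0.594, 0.758 and 0.157 between LN511 and Mat, 0.552, 0.725 and 0.097 between LN111 and Mat, and 0.493, 0.556 and 0.089 between LN111 and LN511. Only LN511 with Mat passed the preset bound of 0.1 for every pair, a pattern of the data that no label states. But LN511 replicate 3 correlated more with Mat replicate 1 (0.224) than with Mat replicate 3. LN511 replicate 1 correlated with Mat replicate 3 at 0.573, near its value for the same number. Between LN511 and Mat only number 2 stood apart, so a pairing of numbers 1 and 3 is not shown. Mat replicates 1 and 3, on different slides, differed by an SD of 0.117 (log2) over 1137 repeatedly printed probes, against 0.026 from their spots and 0.337 to 0.649 for other replicate pairs. Noise between arrays exceeds that between spots (7 spike-in probes of this pair differed by an SD of 0.082), so 1 RNA sample hybridised to 2 slides is not excluded. They were kept as 2 arrays, but Mat may hold fewer than 3 independent samples. Averaging them was among the alternatives added after seeing the data.

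Alternatives were normexp background correction (offset 50), quantile scaling, the deposited value table without scaling, no filter and a stricter filter on dim probes, the mean of probes, a trended and robust prior, the replicate number and the slide as blocks, other sets of arrays in the fit, a 2-fold threshold, and leaving out each array in turn. Chosen after seeing the data were the value table scaled to the 75th percentile, array weights, raising every signal to its array's lowest one well above background, leaving out the 3 cultured arrays numbered 2, and for lists and named genes other sets of arrays in the fit. Overlap between comparisons that share the MH arrays was not analysed here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and figures.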

Results

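Gene expression was measured in rat small hepatocytes collected 3 h after passage onto laminin-111 (LN111), laminin-511 (LN511) or Matrigel (Mat), and in freshly isolated mature hepatocytes (MH), with 3 arrays in each group. Between 52.18% and 62.75% of the 58717 non-control spots of an array were well above background, and 0 spots were saturated. The 75th percentile of the processed signal was 757 to 961 in MH, 1130 to 1370 in LN511, 1340 to 2150 in LN111 and 1920 to 3090 in Mat. LN111 replicate 3 was a noisier array, with a coefficient of variation of repeated probes of 11.1% and 1126 spots with an outlier mark (3.16% to 4.21% and 350 to 499 on the other arrays). In a principal component analysis the MH arrays lay at 230.4 to 237 on the first component, which held 75.3% of the variance, and the cultured arrays at -102.6 to -59.1.

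**Figure D1:**
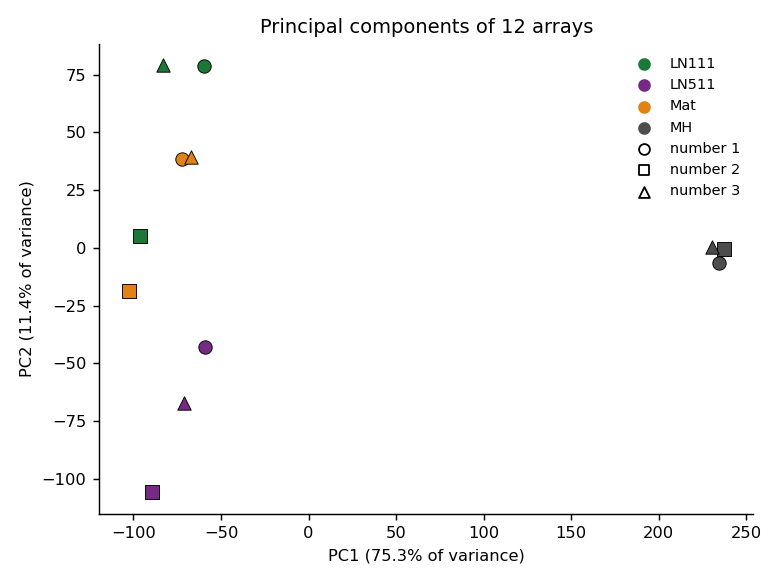
Principal component analysis of the 12 arrays (log2 signal relative to the 75th percentile, genes tested), with the first component (75.3% of variance) on the x axis and the second (11.4%) on the y axis, 1 point per array. The 3 MH arrays sit at 230.4 to 237 on the first component and the 9 cultured arrays at or below -59.1.

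The first comparison set the 9 cultured arrays against the 3 MH arrays, the study's control. Among the 10 largest increases under the named-gene rule, Krt7 and Krt19, keratins of biliary epithelium, were at least 650-fold (limma adjusted p = 2.82e-07) and at least 563-fold higher (adjusted p = 5.12e-07), and the tight junction gene Cldn4 at least 582-fold (adjusted p = 6.07e-10). Col1a1, a fibrillar collagen, rose by 9.96 ± 0.62 log2 (adjusted p = 2.35e-07), S100a4 by 9.82 ± 0.36 (adjusted p = 6.63e-09, other probes from 2.72) and Ccl2 by 9.72 ± 0.60 (adjusted p = 2.21e-07). Ccl7 was at least 356-fold higher (adjusted p = 3.01e-06), Tent5b at least 413-fold (adjusted p = 6.95e-10) and Vom2r-ps135 at least 813-fold (adjusted p = 5.59e-09). Saal1 rose by 10.43 ± 1.10 (adjusted p = 1.14e-05). The names of Saal1 and Vom2r-ps135 each rest on 1 probe named by the array's file and were not checked against the sequence. On MH, Saal1, Col1a1, S100a4 and Ccl2 were well above background on 1 of 3 arrays, and with every signal raised to background their differences were 10.42, 9.33, 9.82 and 9.72. Among genes added because they were measured in both groups, S100a6 rose by 9.48, Msln by 8.66, Anxa1 by 8.56 and Ccn2 by 8.47. Of the genes named in every comparison, the sort marker Cd44 was at least 403-fold higher (adjusted p = 5.62e-10), Itga3 at least 33.5-fold (adjusted p = 8.84e-08) and Sox9, a progenitor transcription factor, at least 69.5-fold (adjusted p = 1.13e-08, other probes from 1.38). Epcam rose by 3.99 ± 0.24 (adjusted p = 1.99e-07), Itgb1 by 1.46 ± 0.11 (adjusted p = 8.8e-07) and Itga6 by 1.31 ± 0.30 (adjusted p = 0.00262). Afp (1.89 ± 0.90, adjusted p = 0.0815) and Dag1 (-0.16 ± 0.10, adjusted p = 0.195) did not pass. Afp passed without LN511 replicate 2 (adjusted p = 0.0183) or Mat replicate 2 (adjusted p = 0.0431), and Dag1 stood at 0.83 under quantile scaling and 0.89 in unscaled values. The proliferation marker Mki67 rose by 1.10 ± 0.45 (adjusted p = 0.0492). Its call was lost without LN111 replicate 2 or 3, LN511 replicate 1 or 2, Mat replicate 1, 2 or 3 or MH replicate 1 or 2 (adjusted p = 0.0758, 0.0705, 0.0772, 0.0702, 0.0653, 0.0769, 0.054, 0.196 and 0.266 in that order), and without MH replicate 2 or 3 its value was 0.63 or 1.84. With the slide as a block Mki67 did not pass (1.52, adjusted p = 0.146).

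Among the 10 largest decreases, the cytochromes Cyp2c13 and Cyp3a2 were at least 12700-fold (adjusted p = 3.24e-10) and at least 9440-fold lower (adjusted p = 6.07e-10), and the sulfotransferase Sult1e1 at least 8760-fold (adjusted p = 4.96e-12). Cyp4a2 fell (-14.13 ± 0.34, adjusted p = 7.6e-10), Serpina3c (-13.92 ± 0.76, adjusted p = 8.94e-08), Apof (-13.10 ± 0.47, adjusted p = 6.14e-09) and Sult1c3 (-12.84 ± 0.54, adjusted p = 1.54e-08). Of the 9 cultured arrays, Cyp4a2 was well above background on 2, Serpina3c on 3, Apof on 1 and Sult1c3 on 2, and with every signal raised to background the differences were -13.47, -13.47, -12.63 and -12.29 in that order. The major urinary protein genes Mup4l3, Mup4l1 and Mup5 fell (-12.80 ± 0.84, -12.38 ± 0.53 and -12.37 ± 0.58, adjusted p = 3.34e-07, 1.86e-08 and 3.3e-08), each well above background on 8 of 9 cultured arrays. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at least 47.9-fold lower (adjusted p = 3.58e-05), and the hepatocyte regulator Hnf4a fell (-1.88 ± 0.31, adjusted p = 0.000277). The bound for Cyp7a1 rests on the mean of unlike MH arrays, at 1.35, -4.27 and -0.79 for MH replicates 1 to 3. Alb, the gene of albumin, fell (-1.37 ± 0.16, adjusted p = 2.3e-05), though under quantile scaling it stood at 0.13.

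Over all genes, 13796 of 18953 changed between cultured cells and MH by limma, 5833 higher and 7963 lower (42.3% higher), and 9346 of them by at least 2-fold. The higher and lower calls were 3557 and 9728 with normexp (26.8% higher), 7907 and 6181 with quantile scaling (56.1%) and 10884 and 3061 in unscaled values (78%). The median of all genes moved from -0.18 to -0.40, 0.18 and 0.86 in that order, so changes are relative to these medians. With the slide as a block 10034 genes changed. Of the called genes with 2 or more usable probes, 365 of 2786 had probes of opposite sign. Culture, sorting, passage and the lack of a fresh isolation all separate these groups at once.

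Of 34 gene lists, 24 changed, 14 higher and 10 lower, by camera, and 1 with an estimated correlation (31 by fry). That 1 list was the hepatic progenitor and biliary markers, of which 26 of 31 tested rose and 1 fell (median 4.18, or 4 with genes at their bounds, camera adjusted p = 1.05e-08, adjusted p = 0.0223 with an estimated correlation). The list included Sox4, up by 5.59 ± 0.14 (adjusted p = 8.52e-10). Its risen members, like those of the integrins and other matrix receptors, also include the sort marker Cd44, whose rise is not a finding. Of the keratins, actin and tubulin cytoskeleton, 28 of 35 rose and 2 fell (median 2.13, camera adjusted p = 2.43e-08, adjusted p = 0.0746 with an estimated correlation). Members that rose were S100a10 (6.89 ± 0.17) and Anxa5 (5.80 ± 0.14). Of the basement membrane and interstitial matrix list, 21 of 28 rose and 1 fell (median 3.72, 3.2 with bounds, camera adjusted p = 3.79e-08, adjusted p = 0.0598 with an estimated correlation). The laminin chain gene Lama5 was at least 197-fold higher, and Lamb1 and Lamc1 rose by 4.32 ± 0.18 and 3.85 ± 0.18. Of the matrix proteases and their inhibitors, 19 of 22 rose and 1 fell (median 2.86, 2 with bounds, camera adjusted p = 1.47e-06, adjusted p = 0.0521 with an estimated correlation). Among those higher were Plat (7.44 ± 0.17) and Timp2 (5.27 ± 0.21). Of the epithelial-mesenchymal transition list, 17 of 25 rose and 1 fell (median 2.30, 2.13 with bounds, camera adjusted p = 4.81e-06, adjusted p = 0.0746 with an estimated correlation). Higher members included Vim, an intermediate filament gene of mesenchymal cells (7.32 ± 0.29).

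Of the immediate-early genes, 27 of 34 rose and 2 fell (median 2.18, 2.09 with bounds, camera adjusted p = 6.57e-07, adjusted p = 0.0874 with an estimated correlation). Its genes included Klf4 (6.68 ± 0.22), Maff (4.65 ± 0.24) and Klf6 (3.38 ± 0.16). Of the YAP/TAZ targets, 16 of 19 rose and 1 fell (median 2.44, camera adjusted p = 1.47e-06, adjusted p = 0.133 with an estimated correlation), with Tgfb2 at least 57.8-fold higher. Ptpn14 was at least 43.7-fold higher, but a second probe, the only one left by the strict filter, gave -1.72. Of the NF-kB and inflammatory genes, 22 of 31 rose and 4 fell (median 1.91, camera adjusted p = 1.13e-05, adjusted p = 0.33 with an estimated correlation), with Cxcl3 at least 314-fold higher and Il1a at least 61.1-fold lower. Of the p53 targets and apoptosis genes, 19 of 28 rose and 2 fell (median 1.14, camera adjusted p = 4.46e-05, adjusted p = 0.0598 with an estimated correlation). Ccng1 rose by 3.37 ± 0.20. Of the integrins and other matrix receptors, 17 of 28 rose and 4 fell (median 1.37, 1.16 with bounds, camera adjusted p = 0.0029, adjusted p = 0.0746 with an estimated correlation), with Itgb6 at least 11-fold higher and Sdc2 down (-3.15 ± 0.12). Of DNA replication genes, 18 of 31 rose and 4 fell (median 0.87, 0.75 with bounds, camera adjusted p = 0.00373, adjusted p = 0.429 with an estimated correlation). Pcna rose by 1.56 ± 0.13, and Cdc6 was at least 1.45-fold higher (-0.19 with normexp). Of focal adhesion genes, 18 of 33 rose and 5 fell (median 0.61, camera adjusted p = 0.00497, adjusted p = 0.299 with an estimated correlation). Higher members included Flna, an actin crosslinker (6.17 ± 0.30). Of Wnt and Notch components, 14 of 25 rose and 7 fell (median 1.58, 1.31 with bounds and -0.59 under the strict filter, camera adjusted p = 0.0302, adjusted p = 0.123 with an estimated correlation). Jag1, a Notch ligand, rose by 4.07 ± 0.30. Of glycolysis and hypoxia genes, 14 of 28 rose and 9 fell (median 0.58, camera adjusted p = 0.0327, adjusted p = 0.299 with an estimated correlation). Ndrg1 rose by 6.30 ± 0.17, and the call of the list was lost without LN511 replicate 2 (adjusted p = 0.0518).

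Lists of hepatocyte function were lower in the cultured cells. Of the cytochromes P450 and phase II enzymes, 35 of 36 fell (median -6.07, camera adjusted p = 9.69e-08, adjusted p = 0.247 with an estimated correlation). Cyp2d4 was among them (-6.48 ± 0.15). All 32 urea cycle and amino acid catabolism genes fell (median -5.42, camera adjusted p = 2.26e-07, adjusted p = 0.299 with an estimated correlation). Lower members included Gls2, a liver glutaminase (-5.58 ± 0.13) and Sds (-8.83 ± 0.47, or -7.91 with signals raised to background). Of the fatty acid oxidation and PPAR-alpha targets, 26 of 27 fell (median -3.46, camera adjusted p = 9e-07, adjusted p = 0.299 with an estimated correlation). Members that fell included Acadm (-4.66 ± 0.14) and Bdh1 (-8.65 ± 0.31, or -8.26 with signals raised to background). Of the secreted plasma proteins, 47 of 49 fell (48 adjusted over the list alone, median -4.23, camera adjusted p = 4.81e-06, adjusted p = 0.454 with an estimated correlation), with Mbl2 down (-9.72 ± 0.69) and Ttr (-1.56 ± 0.15). Of the bile acid genes, 19 of 22 fell and 1 rose (median -6.22, -6.02 with bounds, camera adjusted p = 7.77e-05, adjusted p = 0.181 with an estimated correlation). Nr1h4, the bile acid receptor, fell (-5.87 ± 0.20), and the uptake transporter gene Slco1b2 was at least 989-fold lower. Of the hepatocyte transcription factors, 18 of 22 fell and 1 rose (19 and 1 adjusted over the list alone, median -2.43, camera adjusted p = 0.000335, adjusted p = 0.133 with an estimated correlation). Cebpa was among those that fell (-3.77 ± 0.23). Of the gluconeogenesis and glycogen genes, 13 of 16 fell and 2 rose (median -4.35, camera adjusted p = 0.00325, adjusted p = 0.299 with an estimated correlation). Members that fell included Pck1 (-9.17 ± 0.39) and G6pc1 (-7.74 ± 0.49). Of the fatty acid and triglyceride synthesis genes, 15 of 20 fell and 1 rose (median -1.82, camera adjusted p = 0.0111, adjusted p = 0.401 with an estimated correlation). Fads2, a fatty acid desaturase, fell (-4.35 ± 0.28).

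Markers of other liver cell types moved as well. All 20 tested Kupffer cell and macrophage markers fell (median -5.88, -5.65 with bounds, camera adjusted p = 7.51e-06, adjusted p = 0.28 with an estimated correlation). Clec4f fell (-10.17 ± 0.28, or -9.99 with signals raised to background), and Cd5l was at least 177-fold lower. Of the sinusoidal endothelial markers, 17 of 21 fell and 1 rose (median -2.53, camera adjusted p = 0.000187, adjusted p = 0.181 with an estimated correlation), with Plvap at least 105-fold lower and Tek down (-5.22 ± 0.21, or -5.05 with signals raised to background). The remaining lists did not pass by camera. They were erythroid markers (median -3.16, or -2.51 with bounds, 4 of 6 lower, adjusted p = 0.0511), mitosis genes (0.77, or 0.75 with bounds, 10 of 37 higher and 4 lower, 6 and 4 adjusted over the list alone, adjusted p = 0.0582), epithelial junctions (0.45, 16 of 32 higher and 7 lower, adjusted p = 0.0596) and growth factors and receptors (0.60, or 0.55 with bounds, 19 of 37 higher and 12 lower, adjusted p = 0.0596). Stellate cell and fibroblast markers had a median of 0.24 (0.06 with bounds, 7 of 21 higher and 2 lower, adjusted p = 0.061), with Acta2, a marker of activated stellate cells, up by 2.31 ± 0.28. Lymphocyte and neutrophil markers stood at -1.61 (1 of 9 higher and 7 lower, 2 and 7 adjusted over the list alone, adjusted p = 0.0698), cholesterol synthesis at -0.91 (4 of 25 higher and 14 lower, adjusted p = 0.16) and NRF2 targets at 0.04 (11 of 28 higher and 10 lower, adjusted p = 0.181). The unfolded protein response (-0.48, 8 of 29 higher and 11 lower, adjusted p = 0.88) and heat shock lists (-0.29, 6 of 20 higher and 8 lower, 7 and 9 adjusted over the list alone, adjusted p = 0.88) had medians of the opposite sign to their means and tests. For every other list of this comparison the count adjusted over the list alone equalled that over all genes. No list that passed changed the sign of its median under normexp, quantile scaling or in unscaled values.

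Only Mat had arrays on both slides, so a slide block rested on Mat replicate 3 against Mat replicates 1 and 2. It took up the low hepatocyte signal of Mat replicate 2. Relative to the mean of the cultured arrays, plasma proteins stood at 1.18, -1.61 and 1.27 on Mat replicates 1 to 3. From Mat replicate 1 to 3, across slides, their median differed by 0.11 and that of the urea cycle by 0.05. Lower medians of these lists with the block therefore cannot be put down to the slide. When the slide was a block, the medians of the lists that changed were as follows. They were 4.37 for progenitor markers, 2.72 for the cytoskeleton, 3.57 for matrix, 2.78 for proteases, 2.33 for epithelial-mesenchymal transition, 1.83 for immediate-early genes, 2.60 for YAP/TAZ targets, 1.66 for NF-kB, 1.21 for p53, 1.24 for integrins, 1.01 for DNA replication, 0.72 for focal adhesion, 1.23 for Wnt and Notch and 0.67 for glycolysis. Those that fell stood at -6.84 for P450 enzymes, -6.46 for the urea cycle, -3.56 for fatty acid oxidation, -5.43 for plasma proteins, -6.80 for bile acids, -2.68 for transcription factors, -4.79 for gluconeogenesis, -2.08 for fatty acid synthesis, -5.88 for Kupffer and -2.81 for endothelial markers. Within slide 1 (2 Mat and 3 MH arrays) the same lists had, in the same order, medians of 4.23, 2.42, 3.70, 2.95, 2.56, 1.78, 2.20, 1.61, 1.05, 1.51, 0.96, 0.64, 1.09 and 0.45, and -6.75, -5.69, -3.42, -4.56, -6.46, -2.47, -4.67, -1.95, -6.46 and -2.94. Some lists that did not pass in the main fit passed in these, where calls with the block rest on the same Mat arrays. When the slide was a block, erythroid markers (-3.34, adjusted p = 0.0397) and lymphocyte and neutrophil markers (-2.40, adjusted p = 0.0368) did. Within slide 1, mitosis (1.06, adjusted p = 0.0435) and epithelial junctions (0.65, adjusted p = 0.0307) did.

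**Figure D2:**
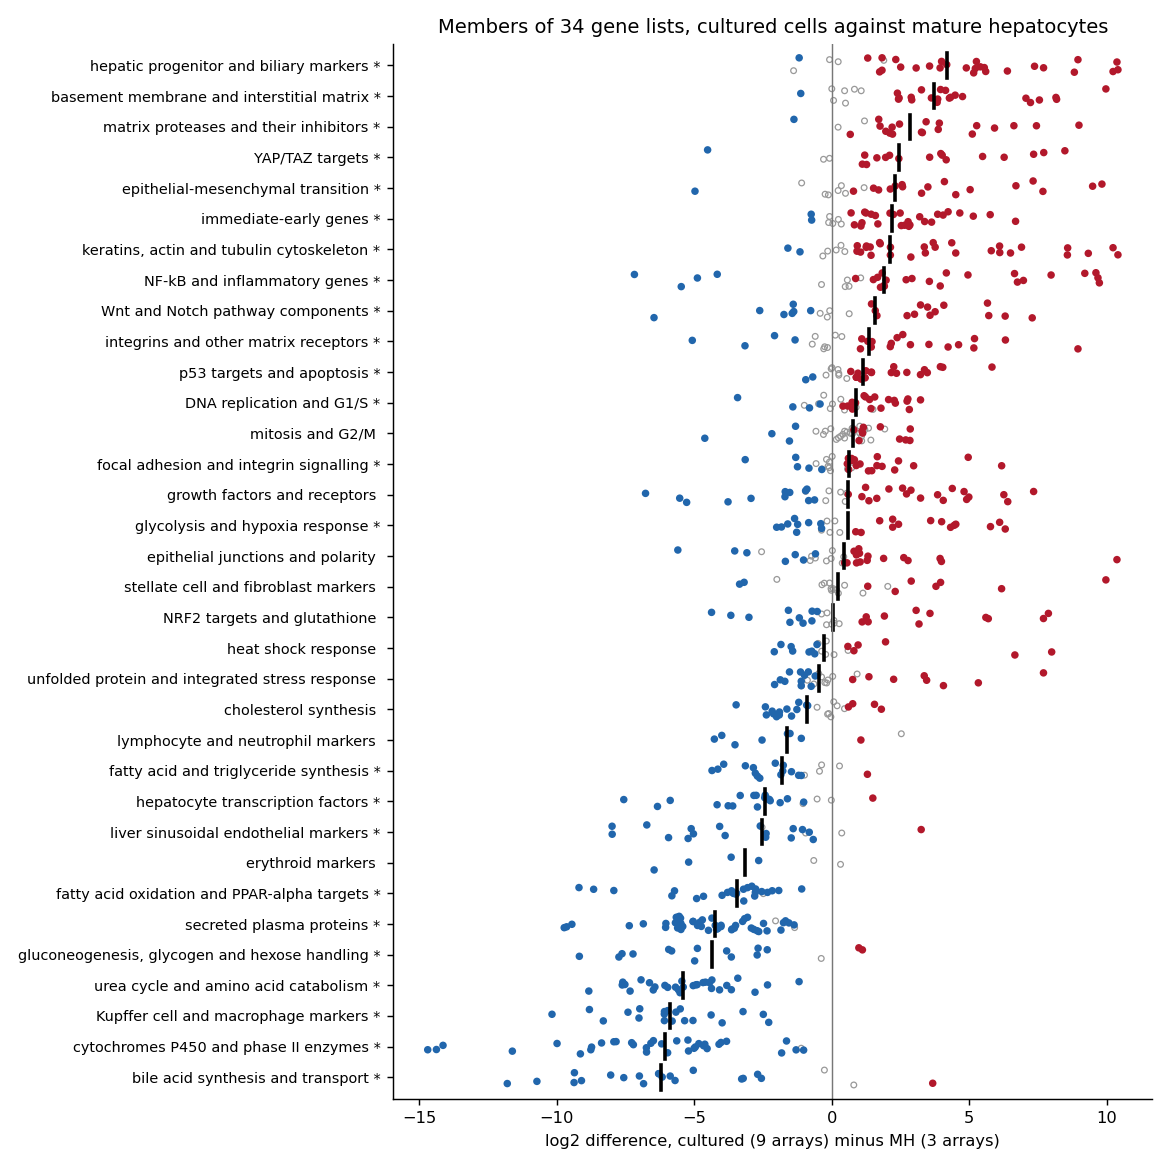
Log2 difference (x axis, cultured minus MH, 9 against 3 arrays) of each tested member of the 34 gene lists (y axis), with a bar at each list's median. Red points passed limma's test as higher, blue points as lower, open grey points did not pass, and an asterisk marks lists with a camera adjusted p under 0.05. Progenitor and biliary markers have a median of 4.18 and the cytochromes P450 and phase II enzymes one of -6.07.

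Each substrate was then set against MH on its own, with 3 arrays against 3. Col1a1 rose by 11.76, 7.62 and 10.50 (SE 0.76) on LN111, LN511 and Matrigel (adjusted p = 5.04e-07, 1.09e-05 and 1.13e-06), and Epcam by 3.08, 4.75 and 4.15 (SE 0.30, adjusted p = 8.61e-06, 4.2e-07 and 1.05e-06). Itgb1, the integrin beta 1 chain, rose by 1.57, 1.36 and 1.45 (SE 0.13, adjusted p = 3.4e-06, 9.62e-06 and 6.11e-06). Itga6, a chain of laminin-binding integrins, rose by 1.86 on LN511 and 1.46 on Matrigel (SE 0.37, adjusted p = 0.00117 and 0.0052) and stood at 0.60 on LN111 (adjusted p = 0.174). Acta2 rose by 4.16 on LN111 and 2.48 on Matrigel (SE 0.35, adjusted p = 3e-06 and 0.000118) and stood at 0.28 on LN511 (adjusted p = 0.493). Twist1 rose by 6.79 and 5.39 on LN111 and Matrigel (SE 0.82, adjusted p = 4.02e-05 and 0.000202) and stood at 1.34 on LN511 (adjusted p = 0.17). Twist1 was well above background on only 1 of 3 LN511 arrays, and its mean in MH was lower still. These values are not bounds, so their size rests on signal near background. Alb fell (-1.45, -0.92 and -1.74, SE 0.20, adjusted p = 8.76e-05, 0.00183 and 2.41e-05) as did Hnf4a (-1.76, -2.53 and -1.34, SE 0.38, adjusted p = 0.00192, 0.000176 and 0.00933). Afp (0.62, 2.71 and 2.34, adjusted p = 0.637, 0.0501 and 0.0836), Dag1 (-0.22, -0.11 and -0.14, adjusted p = 0.154, 0.466 and 0.335) and Mki67 (1.00, 1.15 and 1.15, adjusted p = 0.137, 0.0903 and 0.09) passed on none. Differences between substrates are tested only in the comparisons among the 9 cultured arrays.

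Of 18953 genes, 12650 changed between LN111 and MH (5108 higher and 7542 lower), 12811 between LN511 and MH (5901 and 6910) and 12748 between Mat and MH (4972 and 7776). With the slide as a block 8155, 8400 and 11822 genes changed, and within slide 1, where only Mat met MH, 11732 of 18898 did. The share of calls that were higher was 40.4%, 46.1% and 39%. It became 25.1%, 35.2% and 21.8% with normexp, 55.7%, 55.9% and 56% with quantile scaling and 76.5%, 65.1% and 86.8% in unscaled values. The median of all genes was -0.23, -0.10 and -0.26 in the main setting and 0.78, 0.41 and 1.34 in unscaled values. Probes of opposite sign were seen in 331 of 2554, 338 of 2580 and 314 of 2575 called genes with 2 or more usable probes.

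Next, cells on LN111 were compared with cells on LN511, all 6 arrays on slide 2. Twist1, a transcription factor of mesenchymal cells, rose by 5.45 ± 0.91 log2 (limma adjusted p = 0.0076), Tnn by 5.39 ± 0.95 (adjusted p = 0.00871), Mrgprf by 5.39 ± 0.87 (adjusted p = 0.00673), the smooth muscle actin gene Actg2 by 5.36 ± 0.64 (adjusted p = 0.00334) and Rnase2 by 5.35 ± 1.48 (adjusted p = 0.0419). Twist1, Mrgprf and Rnase2 were well above background on 1 of 3 LN511 arrays. With every signal raised to background their differences were 5.07, 4.59 and 4.35, and Rnase2 did not pass (adjusted p = 0.0511). The lipid transporter gene Abca12 fell (-4.75 ± 0.54, adjusted p = 0.0029), Apcdd1l (-4.70 ± 0.53, adjusted p = 0.0029), Arid3a (-4.14 ± 0.42, adjusted p = 0.00216), Il24 (-4.07 ± 1.17, adjusted p = 0.0483) and S100g (-4.04 ± 1.00, adjusted p = 0.0293). The progenitor markers Epcam and Sox9 were lower on LN111 (-1.67 ± 0.33, adjusted p = 0.0127, and -1.63 ± 0.39, adjusted p = 0.0262). Among the laminin receptor genes, Itga6 stood at -1.27 ± 0.39 (adjusted p = 0.0613), Itga3 at -1 ± 0.46 (adjusted p = 0.176), Itgb1 at 0.21 ± 0.14 (adjusted p = 0.327) and Dag1 at -0.11 (adjusted p = 0.615), none of which passed. Alb (-0.53 ± 0.20, adjusted p = 0.113), Afp (-2.09 ± 1.21, adjusted p = 0.267), Krt19 (-1.28 ± 0.93, adjusted p = 0.377), Hnf4a (0.77 ± 0.40, adjusted p = 0.218), Cd44 (0.23 ± 0.16, adjusted p = 0.349) and Mki67 (-0.15, adjusted p = 0.779) did not pass either. Cyp7a1 was not well above background on all 3 arrays of any substrate and was not tested among substrates.

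Over all genes, 3202 of 17932 changed between LN111 and LN511 by limma, 1096 higher and 2106 lower on LN111 (34.2% higher). The split was 674 and 2167 with normexp (23.7%), 1511 and 1507 with quantile scaling (50.1%) and 1526 and 449 in unscaled values (77.3%), and the median of all genes was -0.15, -0.21, -0.02 and 0.34 in that order. Without LN511 replicate 2 or 3 the count was 2030 or 1848, with the slide as a block 2515, and on slide 2 alone 1745. The call of Il24 was lost without LN111 replicate 1 or 3, LN511 replicate 1, 2 or 3, or Mat replicate 1 or 3 (adjusted p = 0.127, 0.139, 0.0898, 0.139, 0.0912, 0.0673 and 0.0627 in that order). That of Rnase2 was lost without LN111 replicate 1 or 3, LN511 replicate 2 or 3, or Mat replicate 1 or 3 (adjusted p = 0.113, 0.12, 0.124, 0.131, 0.0611 and 0.0605). S100g lost its call without LN111 replicate 1 or 3, LN511 replicate 2 or 3 or Mat replicate 1 (adjusted p = 0.0802, 0.0811, 0.09, 0.0939 and 0.0501), and Sox9 without LN111 replicate 1 or 3 or LN511 replicate 1, 2 or 3 (adjusted p = 0.0756, 0.0772, 0.0573, 0.0705 and 0.0849). Without LN111 replicate 2, Itga6 and Itga3 passed (adjusted p = 0.0131 and 0.0483). In the fit with the slide as a block Il24 and Rnase2 did not pass (adjusted p = 0.061 and 0.0587). Probes of opposite sign were seen in 29 of 596 called genes with 2 or more usable probes. A moderated F test over the 3 substrates called 2320 genes, 1266 with the slide as a block, and 1360, 1110, 1112 and 1373 without LN511 replicate 1, 2 or 3 or Mat replicate 1.

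**Figure D3:**
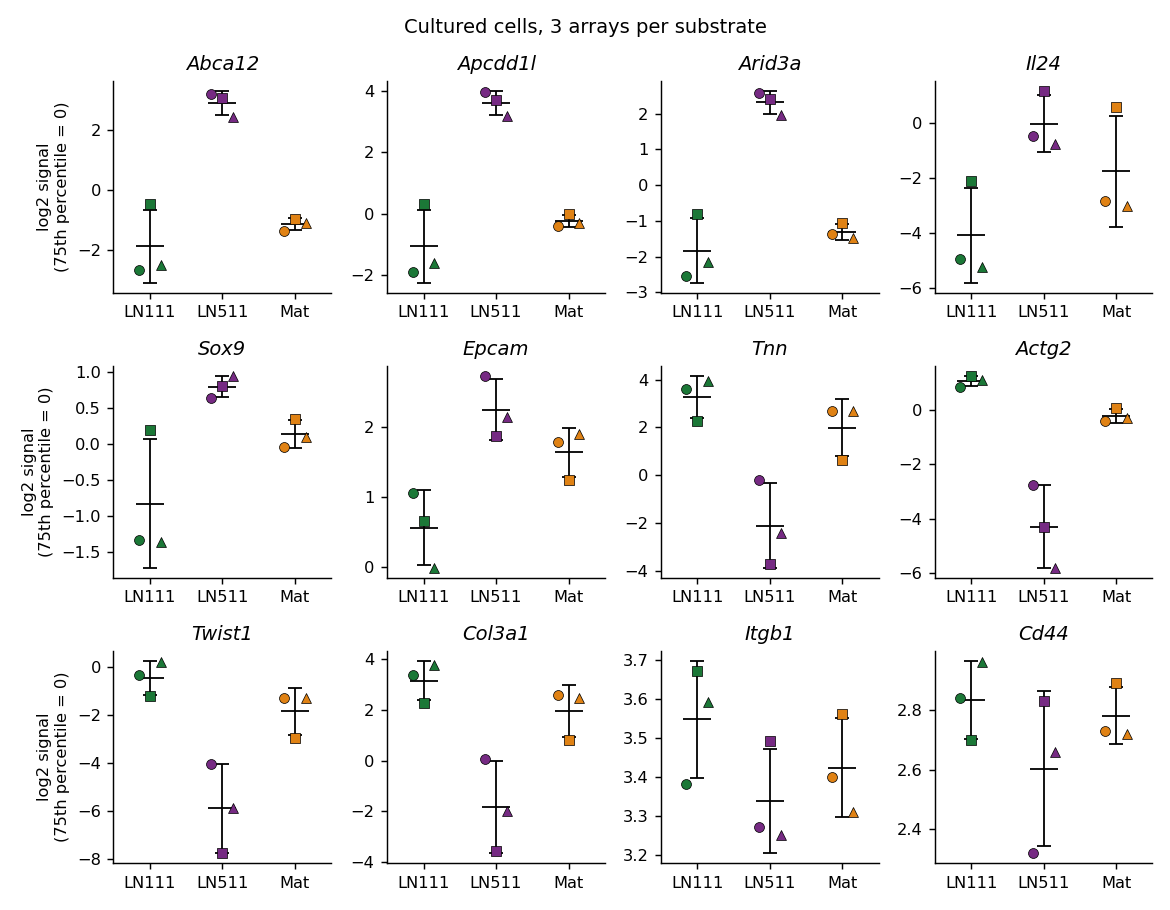
Log2 signal relative to the 75th percentile (y axis) of 12 genes on LN111, LN511 and Matrigel (x axis), 3 arrays per group, with the marker shape giving the replicate number and the bar the mean ± SD. Twist1, Tnn and Actg2 lie higher on LN111 than on LN511 by 5.45, 5.39 and 5.36, and Abca12 and Arid3a lower by -4.75 and -4.14.

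Of 33 lists, 8 changed between LN111 and LN511 by camera (0 with an estimated correlation, 9 by fry). Of the stellate cell and fibroblast markers, 13 of 20 rose on LN111 and 0 fell (17 and 0 adjusted over the list alone, median 3.29, camera adjusted p = 2.94e-11, adjusted p = 0.182 with an estimated correlation). Acta2 rose by 3.88 ± 0.39 (adjusted p = 0.00216), Pdgfrb by 4.32 ± 0.59 (adjusted p = 0.00418) and Thy1 by 1.90 ± 0.24 (adjusted p = 0.00363), and Postn was at least 3.4-fold higher. Of the matrix list, 17 of 28 rose and 1 fell (17 and 4 over the list alone, median 2.08, camera adjusted p = 2.19e-08, adjusted p = 0.182 with an estimated correlation). Among those higher were Col15a1 (4.80 ± 0.59), Loxl2 (4.16 ± 0.50), Nid1 (4.04 ± 0.45) and Col5a1 (3.15 ± 0.33). Of the epithelial-mesenchymal transition list, 12 of 25 rose and 0 fell (14 and 0 over the list alone, median 1.10, camera adjusted p = 2.19e-08, adjusted p = 0.182 with an estimated correlation). Higher members included Tpm2 (4.64 ± 0.57) and Tagln (2.97 ± 0.45). Of the matrix proteases, 8 of 22 rose and 1 fell (10 and 2 over the list alone, median 0.55, camera adjusted p = 0.00296, adjusted p = 0.254 with an estimated correlation), with Mmp2 up by 3.42 ± 0.47 and the urokinase gene Plau down (-2.29 ± 0.42). Its median was 0.93, 0.26 and 0.35 without LN111 replicate 2 or 3 or LN511 replicate 2. Of the endothelial markers, 3 of 14 rose (4 over the list alone, median 0.73, camera adjusted p = 0.011, adjusted p = 0.427 with an estimated correlation). Eng rose by 3.71 ± 0.71, and the call of the list was lost without LN111 replicate 3 (adjusted p = 0.0745), while the median was 0.44 without Mat replicate 2. Flt1, up by 4.35 ± 1.05 (adjusted p = 0.0274, or 3.97 with signals raised to background), lost its call without LN111 replicate 1 or 3 or LN511 replicate 2 or 3 (adjusted p = 0.0799, 0.0822, 0.0748 and 0.0749). Of the integrins and other matrix receptors, 6 of 27 rose and 1 fell (9 and 2 over the list alone, median 0.21, camera adjusted p = 0.015, adjusted p = 0.182 with an estimated correlation). Itga11 was at least 11.5-fold and Itga4 at least 5.25-fold higher, the collagen receptor gene Ddr2 rose by 3.15 ± 0.56 and Itgb6 fell (-1.70 ± 0.29). The list's call was lost without LN111 replicate 2 (adjusted p = 0.0526) and with the replicate number as a block (adjusted p = 0.0801).

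Immediate-early and epithelial junction genes were lower on LN111 than on LN511. Of the immediate-early genes, 19 of 34 fell and 1 rose (20 and 1 adjusted over the list alone, median -0.87, camera adjusted p = 4.52e-05, adjusted p = 0.394 with an estimated correlation). Members that fell included Btg2 (-1.89 ± 0.15, adjusted p = 0.00134), Ier2 (-1.40 ± 0.16, adjusted p = 0.00301), Klf6 (-1.29 ± 0.13, adjusted p = 0.00222) and Maff (-1.03 ± 0.12, adjusted p = 0.00325). Of the epithelial junction genes, 16 of 32 fell and 0 rose (19 and 1 over the list alone, median -1.16, camera adjusted p = 9.23e-05, adjusted p = 0.49 with an estimated correlation). Among those lower were the tight junction genes Cldn4 (-2.55 ± 0.30) and Ocln (-1.75 ± 0.26), and the polarity genes Pard6b (-2.13 ± 0.21) and Crb3 (-1.84 ± 0.27). Progenitor and biliary markers had a median of -1.19 and did not pass (camera adjusted p = 0.277). On slide 2 alone the medians of the lists that changed were 3.17 for stellate markers, 2.08 for matrix, 1.10 for epithelial-mesenchymal transition, 0.55 for proteases, 0.44 for endothelial markers, 0.21 for integrins, -0.87 for immediate-early genes and -1.16 for junctions. As a block, the slide gave 3.29 for stellate and 0.73 for endothelial markers and otherwise equal to those on slide 2. No median of these lists changed sign under normexp, quantile scaling or in unscaled values.

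Cells on LN511 were also compared with cells on Matrigel, the coating on which they had been grown. Abca12 rose on LN511 by 4.02 ± 0.54 log2 (limma adjusted p = 0.00456), the prohormone convertase gene Pcsk1 by 3.94 ± 0.76 (adjusted p = 0.019), Apcdd1l by 3.87 ± 0.53 (adjusted p = 0.00509), Or10al7 by 3.78 ± 0.53 (adjusted p = 0.00569) and Arid3a, named after its value was seen, by 3.62 ± 0.42 (adjusted p = 0.00274). Vom2r70 was at least 8.05-fold higher (adjusted p = 0.00176). Tnn fell (-4.11 ± 0.95, adjusted p = 0.0371), Actg2 (-4.09 ± 0.64, adjusted p = 0.00849), Twist1 (-4.05 ± 0.91, adjusted p = 0.0343), the fibrillar collagen gene Col3a1 (-3.79 ± 0.91, adjusted p = 0.0427) and Mrgprf (-3.65 ± 0.87, adjusted p = 0.0412). Twist1 and Mrgprf were well above background on 1 of 3 LN511 arrays, and Pcsk1 and Or10al7 on 1 and 2 of 3 Mat arrays. With every signal raised to background these 4 genes passed, at -3.68, -2.85, 3.77 and 3.38 in that order. Alb rose by 0.82 ± 0.20 (adjusted p = 0.0471) but stood at -0.28 in unscaled values, so its rise cannot be told apart from the scaling of a bright signal. Hnf4a (-1.19 ± 0.40, adjusted p = 0.119), Epcam (0.60 ± 0.33, adjusted p = 0.354), Itga3 (0.46, adjusted p = 0.651), Itga6 (0.40, adjusted p = 0.636), Itgb1 (-0.09, adjusted p = 0.786), Dag1 (0.03, adjusted p = 0.925), Cd44 (-0.18 ± 0.16, adjusted p = 0.597), Afp (0.37, adjusted p = 0.913), Krt19 (0.48, adjusted p = 0.84) and Mki67 (0, adjusted p = 0.997) did not pass. Sox9 (0.67, adjusted p = 0.385) passed without LN111 replicate 2 (adjusted p = 0.039). The call of Pcsk1 was lost without LN511 replicate 1, 2 or 3 or Mat replicate 1 or 3 (adjusted p = 0.056, 0.0678, 0.0534, 0.0823 and 0.0668 in that order). Those of Tnn and Twist1 were lost without LN111 replicate 1, LN511 replicate 2 or 3 or Mat replicate 1 or 3 (adjusted p = 0.0539, 0.098, 0.114, 0.143 and 0.126 for Tnn, and 0.0515, 0.0715, 0.0986, 0.132 and 0.116 for Twist1). Mrgprf lost its call without these arrays (adjusted p = 0.0573, 0.126, 0.133, 0.155 and 0.139) or LN111 replicate 3 (adjusted p = 0.0533). Col3a1 lost its call without LN111 replicate 1, 2 or 3, LN511 replicate 2 or 3, or Mat replicate 1, 2 or 3 (adjusted p = 0.0618, 0.0518, 0.0544, 0.0991, 0.124, 0.159, 0.0517 and 0.139). Alb lost it without LN111 replicate 1 or 2, LN511 replicate 1, 2 or 3, or Mat replicate 1, 2 or 3 (adjusted p = 0.0637, 0.0582, 0.125, 0.0618, 0.147, 0.164, 0.129 and 0.0508).

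Over all genes, 1471 of 17932 changed between LN511 and Mat by limma, 1264 higher and 207 lower on LN511 (85.9% higher). The split was 760 and 378 with quantile scaling (66.8%) and 447 and 10537 in unscaled values (4.1%), and the median of all genes was 0.12, -0.03 and -0.98 in that order. With the replicate number as a block, 2386 genes changed (1790 higher and 596 lower), 1447 of the 1471 among them. When the slide was a block 131 genes changed, and on slide 2 alone 86 did. Both rest on Mat replicate 3, the 1 Mat array on slide 2, with the spread on slide 2 taken from the other groups. Of the named genes, only Or10al7 and Vom2r70 passed with that block (adjusted p = 0.0169 and 0.0463), and Abca12, Apcdd1l, Arid3a, Actg2, Pcsk1, Mrgprf, Tnn, Twist1, Col3a1 and Alb did not (adjusted p = 0.0818, 0.0818, 0.0544, 0.13, 0.182, 0.2, 0.205, 0.209, 0.237 and 0.505). Their values with that block were 3.99, 3.95, 3.81, -3.98, 4.15, -4.38, -4.79, -4.62, -4.31 and 0.51 in that order. Without LN511 replicate 2 or 3 the count was 770 or 894, and without Mat replicate 1, 2 or 3 it was 636, 946 or 837. With Mat replicates 1 and 3 averaged and counted once, which treats them as 1 sample, 751 genes changed and 5 of the 10 named genes kept their calls. Probes of opposite sign were seen in 18 of 192 called genes with 2 or more usable probes.

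Of 33 lists, 10 changed between LN511 and Mat by camera, 1 higher and 9 lower (0 with an estimated correlation, 2 by fry). With quantile scaling 2 lists were higher and 6 lower (7 of them shared), in unscaled values 4 and 3 (5 shared) and with normexp 1 and 15 (10 shared). Of the immediate-early genes, 13 of 34 rose and 0 fell (18 and 1 adjusted over the list alone, median 0.79, camera adjusted p = 1.3e-05, adjusted p = 0.332 with an estimated correlation). Higher members included Dusp1 (1.40 ± 0.18), Btg2 (1.32 ± 0.15), Maff (0.93 ± 0.12) and Klf6 (0.92 ± 0.13). In unscaled values the list stood at -0.31, Maff at -0.17 and Klf6 at -0.18. Of the stellate cell and fibroblast markers, 6 of 20 fell and 0 rose (10 and 0 over the list alone, median -2.09, -2.03 with bounds, camera adjusted p = 1.83e-10, adjusted p = 0.254 with an estimated correlation). Members that fell included Pdgfrb (-2.94 ± 0.59), Col1a1 (-2.88 ± 0.61) and Acta2 (-2.20 ± 0.39). Postn was at least 1.97-fold lower but stood at 0.10 with normexp and did not pass with signals raised to background (adjusted p = 0.104), and the median of the list was -1.14 without LN511 replicate 2. Of the matrix list, 9 of 28 fell and 0 rose (14 and 1 over the list alone, median -1.02, camera adjusted p = 1.86e-08, adjusted p = 0.247 with an estimated correlation). Among those lower were Col15a1 (-3.30 ± 0.59), Loxl2 (-2.71 ± 0.50), Nid1 (-2.62 ± 0.45) and Col5a1 (-2 ± 0.33). Of the epithelial-mesenchymal transition list, 4 of 25 fell and 0 rose (10 and 1 over the list alone, median -0.54, camera adjusted p = 6.73e-06, adjusted p = 0.254 with an estimated correlation). Lower members included Tpm2 (-3.10 ± 0.57) and Lgals1 (-1.60 ± 0.31). Mmp2 (-2.20 ± 0.47) and Mmp23 (-1.96 ± 0.39) fell among 22 matrix proteases, as 2 of them (4 over the list alone, median -0.39, or 0.12 with normexp, camera adjusted p = 0.00295, adjusted p = 0.254 with an estimated correlation). Of the integrins and other matrix receptors, 1 of 27 fell, Itga11, at least 3.55-fold lower (camera adjusted p = 0.00822, adjusted p = 0.247 with an estimated correlation). The median of that list was 0.00 (0.07 with normexp, -0.18 with quantile scaling and -1.09 in unscaled values) while its mean and test were lower. Once the slide was a block, no member named here passed (limma), at 1.56 for Dusp1 (adjusted p = 0.0565), 1.24 for Btg2 (adjusted p = 0.0625), 0.93 for Maff (adjusted p = 0.0818) and 0.96 for Klf6 (adjusted p = 0.0908). Among those lower, that block gave adjusted p = 0.0997 for Postn, 0.156 for Pdgfrb, 0.217 for Col1a1, 0.168 for Acta2, 0.15 for Col15a1, 0.102 for Loxl2, 0.125 for Nid1 and 0.116 for Col5a1 (at -2.06, -3.36, -3.09, -2.18, -3.46, -3.18, -2.82 and -2.13 in that order). It gave adjusted p = 0.161 for Tpm2, 0.218 for Lgals1, 0.2 for Mmp2, 0.155 for Mmp23 and 0.147 for Itga11 (at -3.24, -1.58, -2.46, -2.20 and -1.88).

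In the remaining lists that passed in this comparison, mitosis genes had a median of -0.27 with 0 of 37 members past the test (camera adjusted p = 0.00236, adjusted p = 0.872 with an estimated correlation), and DNA replication genes one of -0.08 (0.02 with normexp) with 0 of 31 (camera adjusted p = 0.0118, adjusted p = 0.872 with an estimated correlation). The cytochromes P450 and phase II enzymes stood at -0.29 with 0 of 28 (camera adjusted p = 0.0452, adjusted p = 0.872 with an estimated correlation), and secreted plasma proteins at -0.32, with Alb the 1 of 46 that passed, as higher (camera adjusted p = 0.0479, adjusted p = 0.896 with an estimated correlation). In unscaled values the P450 and plasma protein lists stood at -1.39 and -1.42, still below the median of all genes (-0.98), while camera, which compares t statistics, had both as higher (adjusted p = 0.387 and 0.0217). Mitosis lost its call without LN511 replicate 3 or Mat replicate 2 (-0.07 and -0.06, adjusted p = 0.128 and 0.0781) and DNA replication without Mat replicate 2 (0.05, adjusted p = 0.184). P450 enzymes lost it without LN511 replicate 2 or 3 or Mat replicate 1 or 3 (0.29, -0.24, 0.04 and 0.08, adjusted p = 0.659, 0.0911, 0.322 and 0.398), and with signals raised to background (-0.19, adjusted p = 0.0795). Plasma proteins lost it without LN111 replicate 2 or 3, LN511 replicate 2 or Mat replicate 1 or 3 (-0.30, -0.32, 0.65, 0.06 and 0.15, adjusted p = 0.0506, 0.051, 0.7, 0.561 and 0.626). Without LN511 replicate 1 or Mat replicate 2 the medians were -0.65 and -0.90 for P450 enzymes and -1.06 and -1.25 for plasma proteins. With the replicate number as a block the urea cycle list passed too (median -0.24, adjusted p = 0.00942 against 0.119 without the block). With the slide as a block the medians were -2.12 for stellate markers, -1.22 for matrix, -0.52 for epithelial-mesenchymal transition, 0.85 for immediate-early genes, -0.41 for proteases, 0.02 for integrins, -0.79 for P450 enzymes and -1.32 for plasma proteins, and mitosis (-0.06, adjusted p = 0.109) and DNA replication (0.04, adjusted p = 0.194) did not pass. Lists that passed with the slide as a block but not in the fit without a block were the urea cycle (-1.01, adjusted p = 0.0019), fatty acid synthesis (-0.20, adjusted p = 0.0233) and the unfolded protein response (-0.18, adjusted p = 0.0134). On slide 2 alone the lists called without a block stood at -2.12, -1.22, -0.52, 0.82, -0.41, 0.02, -0.96, -1.32, -0.06 and 0.04 in that order. The block and slide 2 alone both set Mat replicate 3, without an array numbered 2, against 3 LN511 arrays of which number 2 is low. As differences from the mean of the 9 cultured arrays, the urea cycle list stood at 0.97 on that Mat array and at 0.91, -1.47 and 0.40 on LN511 replicates 1 to 3, and plasma proteins at 1.27 and at 1.43, -1.98 and 0.39.

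Calls of single members of the lists were also lost in fits without single arrays, which have fewer degrees of freedom. Without Mat replicate 1 the calls of Acta2, Col1a1, Pdgfrb, Lgals1, Loxl2, Mmp2, Mmp23, Tpm2, Col15a1 and Nid1 were lost (adjusted p = 0.0553, 0.105, 0.0961, 0.0811, 0.0691, 0.117, 0.0913, 0.0632, 0.0628 and 0.0568 in that order), at -2.20, -2.83, -2.64, -1.57, -2.59, -2.03, -1.80, -3.07, -3.16 and -2.51. Without LN511 replicate 3 those of Acta2, Col1a1, Pdgfrb, Lgals1, Loxl2, Mmp2, Mmp23 and Tpm2 were lost (adjusted p = 0.05, 0.0932, 0.0756, 0.0685, 0.056, 0.0973, 0.0715 and 0.0571), at -2.02, -2.75, -2.87, -1.42, -2.43, -2.07, -1.90 and -2.92. Without LN511 replicate 2 those of Acta2, Col1a1, Pdgfrb, Lgals1, Loxl2, Mmp2 and Mmp23 were lost (adjusted p = 0.0526, 0.0603, 0.0718, 0.058, 0.0539, 0.0892 and 0.0752), at -2.10, -2.26, -2.50, -1.65, -2.73, -1.88 and -1.77. Without Mat replicate 3 those of Col1a1, Pdgfrb, Lgals1, Loxl2, Mmp2, Mmp23, Tpm2 and Col15a1 were lost (adjusted p = 0.0919, 0.0825, 0.0632, 0.0595, 0.0983, 0.0767, 0.0574 and 0.0535), at -2.77, -2.74, -1.61, -2.47, -2.08, -1.83, -3.03 and -3.22. Without Mat replicate 2 those of Col1a1 and Lgals1 were lost (adjusted p = 0.063 and 0.0573), at -3.03 and -1.62.

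Finally, cells on LN111 were compared with cells on Matrigel. No gene passed by limma (0 of 17932, 2183 at an unadjusted p under 0.05, smallest adjusted p = 0.095). The 5 genes of smallest p among those without a placeholder name, none of which passed, were Otud1 (-1.15 ± 0.16 log2, adjusted p = 0.308), Ano9 (at least 1.97-fold lower, adjusted p = 0.318), Angpt4 (2.03 ± 0.31, adjusted p = 0.318), the secreted glutathione peroxidase gene Gpx3 (1.55 ± 0.24, adjusted p = 0.323) and Ogdhl (1.27 ± 0.21, adjusted p = 0.323). Epcam stood at -1.07 ± 0.33 (adjusted p = 0.337), Sox9 at -0.96 ± 0.39 (adjusted p = 0.393), Itga6 at -0.86 ± 0.39 (adjusted p = 0.429), Krt19 at -0.80 ± 0.93 (adjusted p = 0.723), Afp at -1.72 ± 1.21 (adjusted p = 0.564) and Alb at 0.29 ± 0.20 (adjusted p = 0.562). Itga3 (-0.54, adjusted p = 0.627), Hnf4a (-0.42, adjusted p = 0.655), Mki67 (-0.16, adjusted p = 0.855), Itgb1 (0.12 ± 0.14, adjusted p = 0.719), Dag1 (-0.07, adjusted p = 0.83) and Cd44 (0.05 ± 0.16, adjusted p = 0.902) did not pass. Without LN111 replicate 1, 2 or 3 or Mat replicate 1 the count was 2, 7, 1 or 1. With the slide as a block it was 0 (519 at an unadjusted p under 0.05), and on slide 2 alone, with 1 Mat array and the spread taken from the other groups, it was 37.

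Of 33 lists, 7 changed between LN111 and Mat by camera, 4 higher and 3 lower on LN111 (0 with an estimated correlation, 0 by fry), with no member past the test over all genes. In unscaled values 8 lists were higher and 1 lower (5 of them shared), and with normexp 4 and 7 (7 shared). Stellate cell and fibroblast markers had a median of 1.17 (2 of 20 higher adjusted over the list alone, camera adjusted p = 0.000299, adjusted p = 0.672 with an estimated correlation), with Acta2 at 1.68 ± 0.39 and Thy1 at 0.97 ± 0.24, and 0.76 and 0.61 without LN111 replicate 3 or Mat replicate 2. The matrix list stood at 0.96 (camera adjusted p = 0.00184, adjusted p = 0.537 with an estimated correlation), with Lamb1 at 0.91 ± 0.23. The epithelial-mesenchymal transition list stood at 0.52 (0.30 without LN111 replicate 3, camera adjusted p = 0.000159, adjusted p = 0.534 with an estimated correlation) and endothelial markers at 0.57 (0.24 without LN111 replicate 3, camera adjusted p = 0.00873, adjusted p = 0.537 with an estimated correlation), and in unscaled values these medians were -0.09 and -0.03, where the median of all genes was -0.59. Epithelial junctions stood at -0.66 (2 lower over the list alone, camera adjusted p = 1.96e-08, adjusted p = 0.534 with an estimated correlation), with Crb3 at -1.18 ± 0.27 and Pard6b at -1.01 ± 0.21. Progenitor and biliary markers stood at -0.74 (camera adjusted p = 0.00765, adjusted p = 0.534 with an estimated correlation), though the water channel gene Aqp1 (0.97 ± 0.17), the 1 member past the test over the list alone, was higher. Cholesterol synthesis stood at -0.20 (camera adjusted p = 0.0161, adjusted p = 0.842 with an estimated correlation). Its call was lost without LN111 replicate 2 or 3 or Mat replicate 1 or 3 (adjusted p = 0.352, 0.173, 0.0835 and 0.147), and its median was -0.49 and -0.37 without LN111 replicate 1 or Mat replicate 2. Without LN111 replicate 1, LN511 replicate 1 or Mat replicate 2, 16, 11 or 15 lists changed. With the slide as a block 15 did, among them plasma proteins at -1.41 (adjusted p = 2.75e-05), P450 enzymes at -0.90 (adjusted p = 0.0146) and the urea cycle at -0.82 (adjusted p = 0.00564). That block sets Mat replicate 3, without an array numbered 2, against 3 LN111 arrays. As differences from the mean of the 9 cultured arrays, plasma proteins stood at 1.54, -1.43 and -0.42 on LN111 replicates 1 to 3 and at 1.18, -1.61 and 1.27 on those of Mat. With the replicate number as a block these 3 lists did not pass (adjusted p = 0.0635, 0.316 and 0.228). The others gained were gluconeogenesis (-0.56), fatty acid oxidation (-0.47), fatty acid synthesis (-0.39), immediate-early genes (-0.29) and hepatocyte transcription factors (-0.26). The 7 lists then had medians of 0.64 for stellate markers, 0.69 for matrix, 0.52 for epithelial-mesenchymal transition, 0.54 for endothelial markers, -0.61 for junctions, -0.56 for progenitor markers and -0.39 for cholesterol synthesis. On slide 2 alone these were 0.62, 0.69, 0.52, 0.32, -0.61, -0.56 and -0.39.

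**Figure D4:**
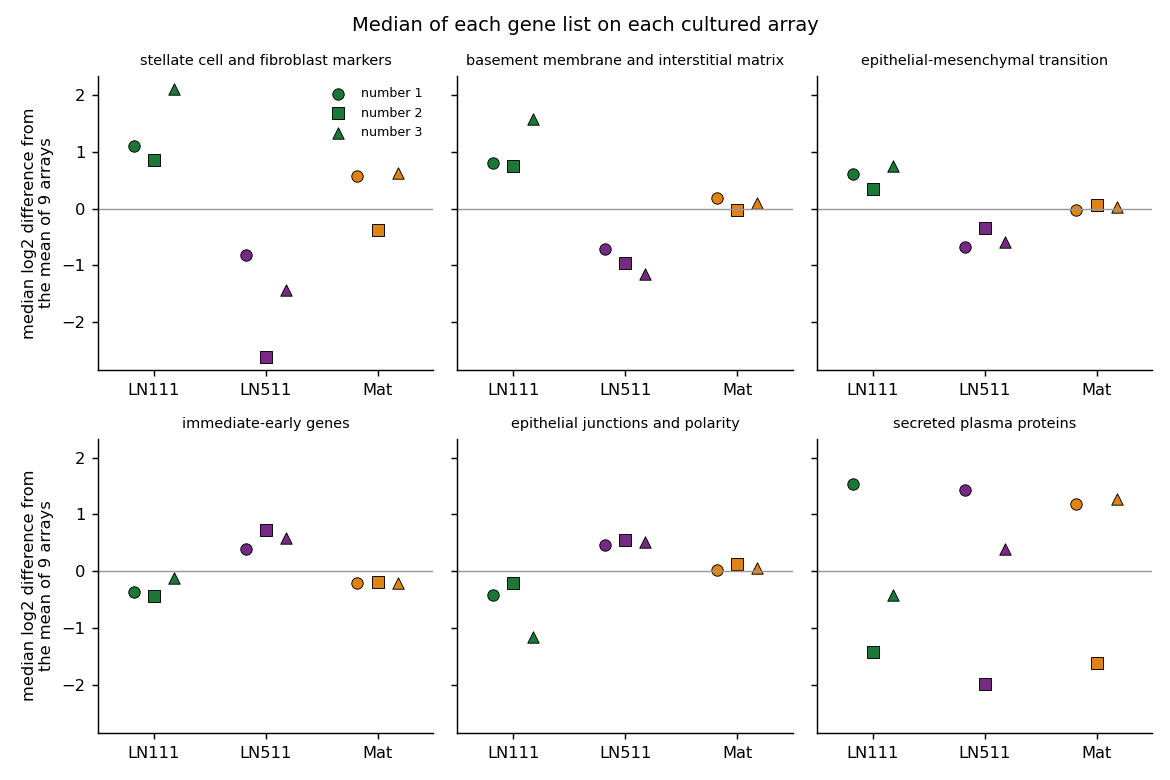
Median log2 difference from the mean of the 9 cultured arrays (y axis) of the tested members of 6 gene lists on each array, by substrate (x axis), with the marker giving the replicate number. Stellate cell and fibroblast markers lie at 1.10, 0.86 and 2.10 on LN111 and at -0.82, -2.61 and -1.43 on LN511, and plasma proteins lie lowest on the arrays numbered 2 of each substrate (-1.43, -1.98 and -1.61).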

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

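The value table scaled to the 75th percentile, array weights, signals raised to background, the fits without the 3 cultured arrays numbered 2 or with Mat replicates 1 and 3 averaged, and for lists and named genes the fits on other sets of arrays were chosen after seeing the data. Of 7592 values of 279 named-gene results under the alternatives, 7216 kept direction and call, 223 lost the call, 93 gained one, 50 changed sign without a call and 10 reversed. Of 1445 values of 49 list results, 1323 kept both, 118 lost the call and 4 reversed. Of the counts of genes and lists, 186 of 227 and 104 of 119 stayed within 1.5 times. Reversed were, with normexp, Cdc6 (-0.19, cultured against MH) and Postn (0.10, LN511 against Mat), with quantile scaling Alb (0.13) and Dag1 (0.83) in cultured against MH, and in unscaled values Dag1 in cultured against MH (0.89) and, in LN511 against Mat, Alb (-0.28), Dag1 (-1.07), Klf6 (-0.18), Maff (-0.17) and the lists of P450 enzymes (-1.39) and plasma proteins (-1.42). The median of all genes was -0.98 there, so that Alb, Klf6 and Maff still stood above it and the medians of both lists below it. For these 2 lists only the direction of camera's t statistics reversed. The strict filter reversed Ptpn14 (-1.72) and the Wnt and Notch list (-0.59), with fewer probes tested, and leaving out LN511 replicate 2 reversed plasma proteins (0.65, range -1.25 to 0.65 leaving out 1 array). In LN511 against Mat the count of 1471 genes became 3556 with normexp, 10984 unscaled, 815 under the strict filter, 131 with the slide as a block, 8126 with array weights, 750 without the arrays numbered 2, 751 with Mat replicates averaged and 636 to 1749 leaving out 1 array. In LN111 against LN511 the 3202 became 2118 at 2-fold, 1975 unscaled, 1908 with only these arrays and 1848 to 4156 leaving out 1 array. In LN111 against Mat the 0 became 1 unscaled, with all 12 arrays and with array weights, and 0 to 7 leaving out 1 array. The F test's 2320 became 6487 unscaled, 1447 under the strict filter, 1266 with the slide as a block, 7142 with array weights, 1468 with Mat replicates averaged and 1110 to 2963 leaving out 1 array. Without a filter more genes were tested, and 22578 (cultured), 19270 (LN111) and 22892 (Mat) differed from MH, while the slide block gave 8155 (LN111) and 8400 (LN511). Lists changed in LN111 against Mat were 0 with an estimated correlation and by fry, 11 with normexp, 19 without a filter, 15 with the slide as a block and 7 to 16 leaving out 1 array. In LN511 against Mat they were 0 with an estimated correlation, 2 by fry, 16 with normexp and 22 without a filter, in LN111 against LN511 0 with an estimated correlation and 14 without a filter, and in cultured against MH 1 with an estimated correlation. With the replicate number as a block, 2386 genes changed in LN511 against Mat, 4877 in LN111 against LN511 and 3899 in the F test, and the integrin list lost its call in LN111 against LN511 (adjusted p = 0.0801). Apart from those changes no list called in the 3 substrate comparisons lost its call with that block. The cause was not tested where none is given. Low signal over background limits genes that are dim in 1 group to bounds on the fold.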

Other observations

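All tests in this part, the fit by replicate number and the exchange of groups within numbers included, were chosen after the results they address were seen. Excepted are the arrangements of the numbers and the other regroupings of arrays in the last paragraph, whose bounds were written before their counts were seen.

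On each substrate, the array numbered 2 had lower signal of many hepatocyte genes than those numbered 1 and 3. In a limma fit with group and number as terms, 904 of 17932 genes differed by number, 491 of them lower and 413 higher in number 2. Adh1c, an alcohol dehydrogenase, was lower by -5.12 ± 0.48 log2 (adjusted p = 0.0212), Tdo2 by -5.10, Cyp1a2 by -4.66, Bhmt by -4.44, the bile salt export pump gene Abcb11 by -4.28, Apoc3 by -4.18 and the coagulation factor gene F9 by -4.02. Of 46 secreted plasma protein genes 30 changed by number, all lower in number 2 (median of the list -2.53, and -1.91 in LN111, -2.81 in LN511 and -2.86 in Mat). Of 27 urea cycle genes 16 changed, 15 of them lower (median -2.03), of 28 P450 and phase II genes 11, 10 of them lower (-1.34), and of 29 NF-kB and inflammatory genes 9, all lower (-0.95). Hepatocyte transcription factors (0.05), progenitor markers (0.15) and immediate-early genes (0.00) had medians near 0. The progenitor and biliary median hides moves both ways, since 7 of 31 members changed by number, 3 of them lower. Krt19 stood at 4.24, 4.74 and 4.31 on the arrays numbered 2 of LN111, LN511 and Mat, and at 0.86 to 3.57 on the other cultured arrays. Afp stood at 2.41, 3.52 and 3.78 there, lower than on the other arrays of each substrate. Higher in number 2 were Ms4a8 (3.47), Guca2a (3.37), Eps8l3 (3.36), Col14a1 (3.13), the bile acid transporter gene Slc51a (3.11) and Il24 (2.76). Chance could not be excluded for this count, since 1 other of 36 arrangements of the numbers within the groups gave more genes (1058), and 2 of 36 gave as many, the labelled one included. Arrangements that exchange only numbers 1 and 3 leave the arrays numbered 2 together and so keep the pattern described. The arrangements therefore cannot decide whether the pattern of number 2 is chance.

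The lower hepatocyte genes in number 2 were weighed against array quality, the slide and the mesenchymal share. The coefficient of variation of repeated probes was 3.53% and 3.16% on the LN111 and Mat arrays, below the median of the other 6 cultured arrays (3.58%). Yet the upper quartiles of plasma protein genes were -1.13 and -1.95 there, which argues against noise between spots. For LN511 (4.21%) such noise stays open. This measure cannot show the quality of the RNA or of its labelling, which stays open on every substrate. Within slide 1, plasma protein genes were lower in Mat replicate 2 than in replicate 1 by a median of -2.80, and the LN111 and LN511 arrays share slide 2, which argues against the slide. Stellate cell markers were lower too in number 2 (-0.95), which argues against more mesenchymal cells there. A shared cell preparation or rat behind each number is a hypothesis that no label states, and no biological explanation was tested.

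Stellate cell and fibroblast markers were higher on LN111 than on LN511 by a median of 3.29. Without the noisier array of LN111 replicate 3 the median was 2.83, which argues against that array as the source. The lowest median under quantile scaling, normexp background correction and unscaled values was 1.98, just short of the bound of 2 set for it. Scaling or background correction as a part of the size therefore stays open. The lower quartile of the markers was 1.85 (Acta2 3.88 and Col1a1 4.14), as different shares of mesenchymal cells would need, but these are the genes of the pattern itself, so cell shares remain a hypothesis without independent support. Of the 24 markers on the array, 6 are in another list, so the list is not distinct. On all MH arrays 14 were well above background, but so were 20 of 21 Kupffer cell and 20 of 22 endothelial markers. Signal in MH therefore does not tell which cells express the stellate markers. A change of expression within the same cells in response to the substrate stays open and was not tested.

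Immediate-early genes were lower on LN111 than on LN511 by a median of -0.87. Without the array of LN111 replicate 3 the median was -1, which argues against the quality of that array as the source. Dilution by mesenchymal cells would lower other transcripts of the hepatocytic and biliary cells. Of 3 lists weighed, progenitor and biliary markers (-1.19) and epithelial junctions (-1.16) stood low and plasma proteins did not (-0.06). Of lists not weighed, P450 enzymes (-0.01), urea cycle (0.08) and bile acid genes (0.05) did not stand low either. Gluconeogenesis genes (-0.33) and hepatocyte transcription factors (-0.45) lay between. A fall shared alike by all these lists was thus not seen, but dilution as a part of the difference stays open. A response to the substrate, or a difference in handling at collection, may underlie the difference and was not tested.

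Regroupings of the same arrays were counted for each comparison. For the genes changed between cultured cells and MH, 1 of 100 splits drawn from 220, the real one, gave as many (13796, highest other split 6300). Most other splits mix MH with cultured arrays, which raises the spread within groups and lowers the count. The labels also do not show that replicates are independent, so these splits do not exclude chance. For the F test over substrates, 1 of 100 splits drawn from 280, the real one, gave as many genes (2320, highest other 2146). Those splits treat the arrays as exchangeable, although deviations from group means were correlated between some LN511 and Mat arrays of the same replicate number. A pairing of LN511 with Mat by every number was not shown. When groups were exchanged only within replicate numbers, 1 of 36 exchanges, the real one, gave as many genes by the F test (highest other 882). Leaving out 1 array brought its count to as few as 1110. Exchanges that part Mat replicates 1 and 3 can raise the spread within groups and lower the count. Chance is therefore not excluded for the F test. Chance was not excluded for the lists of cultured against MH (5 of 100, 24 lists, highest other 29, median of the other splits 15). The 10 splits of 3 arrays against 3 are too few to exclude chance. They gave as large a count of genes in 1 split for LN111 (12650, highest other 1), LN511 (12811, highest other 1) and Mat against MH (12748, highest other 0), for LN511 against Mat (1471, highest other 0) and for LN111 against LN511 (3202, highest other 1), and in 10 splits for LN111 against Mat (0, highest other 17). For lists the number of such splits was 10 in LN111 against Mat (7 lists, highest other 15), 6 in LN511 against Mat (10, highest other 15) and 9 in LN111 against LN511 (8, highest other 16). The other splits had medians of 11, 11 and 14 lists in that order. The real counts lay below these medians, so the number of lists called by camera among substrates does not exceed that of regrouped arrays.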
